A study of Homo sapiens with 8 samples.

How the data were processed

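The series measured messenger RNA in cultured normal human mammary epithelial cells, that is epithelial cells of breast tissue that is not cancerous. Cells were kept for 48 h with 10 µM tamoxifen, a drug that binds the estrogen receptor, or with its vehicle, dimethyl sulfoxide. Total RNA was hybridised as biotin-labelled cDNA to 8 Affymetrix Human Gene 1.0 ST arrays, 4 per group, 1 per sample. The titles call the vehicle samples untreated, and the treatment protocol gives dimethyl sulfoxide for them. Each title gives a repeat number from 1 to 4. Whether the repeats came from separate cultures or donors is not given in the sources used here, so p-values of single genes measure the spread between these arrays, which may be technical.

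The deposited values are log2 expression values per probe set, 1 column per array, and the submitters' processing notes name RMA (robust multi-array average), whose version is not given. That method corrects background, makes the arrays' distributions alike and summarises the probes of a probe set, and it is known to compress fold changes, most of all for dim probe sets. The log2 scale was read from the deposited values, which ran from about 2.5 to 13.2 on every array. No further transformation or normalization was applied before the tests. For arrays there is no count or depth, and the number of arrays limits the precision.

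The table held 29096 probe sets. The platform annotation listed 21214 of them, of which 19460 had 1 gene symbol and 1754 had several. The remaining 7882 were unnamed here. Only probe sets with 1 symbol were named, and symbols were checked through the gene number against the RefSeq gene table of the human assembly GRCh38.p14, which changed 0 of them. Gene numbers of 31 probe sets were not in that table and kept the annotation's symbol. This gave 18417 genes. For the 769 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays stood for the gene. Of the 225 such genes that passed the test, 1 had another probe set past the threshold in the opposite direction. Chromosome names were taken from the same gene table, without positions.

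Tamoxifen was compared with vehicle by limma 3.58.1 in R 4.3.3, with a linear model of the group alone, moderated variances (5.04 prior degrees of freedom) and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all 18417 genes, and genes with an adjusted p under 0.05 were called changed. Genes changed at least 2-fold were counted separately. Log2 fold changes are tamoxifen minus vehicle, errors of group means are standard deviations over 4 arrays, and errors of fold changes are limma's standard errors.

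A set of 35 gene lists was fixed before the data were examined, from pathways and cell types that fit the tissue and the drug. They held 933 different symbols, 834 of which were measured after 46 were renamed, and the others are not analysed in these lists, among them 9 old symbols that fit more than 1 current gene. Each list was tested with limma's camera, which compares its genes with all other genes, at the preset inter-gene correlation of 0.01, and p-values were adjusted over the 35 lists. At this preset the p-values weigh a list's genes against the spread over other genes. They take no account of how strongly its genes vary together between these arrays. Beside it, the members past the genewise test were counted, adjusted over all genes and adjusted over the list alone. Camera with the correlation estimated from the 8 arrays and limma's rotation test fry were run as alternatives. Fry tests only whether a list's genes move, and does not compare them with other genes.

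Genes were named by a rule also fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among changed genes whose groups did not overlap, up to 4 changed members with the smallest p of each list past the camera threshold, the member with the smallest p of every other list, and ESR1, PGR, GREB1, TFF1 and CYP1A1 whatever their values. Of the 4 members, the 2 with the smallest p are given in the text, which makes 67 genes under the rule. Other genes are named where a group had 5 or fewer members on one side, or under the other observations, and these names were chosen after their values were seen. XIST, Y-linked genes and uncharacterised symbols were left out of the rule.

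The script for the gene and list tests was checked on simulated data with the arrays' own means and spreads over 18417 genes. The simulated genes varied independently of each other and lists were drawn at random. The check therefore does not cover genes that vary together, as those of a real list can. Of 50 genes per size of change, 52% were called in the right direction at a log2 change of 0.25, 88% at 0.5, 98% at 1 and 100% at 2. Unchanged genes made up 3.98% of the calls. The simulation changed 200 genes, far fewer than the 5027 called in the data, so these shares need not hold for the data. With no gene changed, 0 genes were called by limma at an adjusted p under 0.05.

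Alternatives set before the data were examined were the repeat number as a block, leaving out each of the 8 arrays in turn, quantile normalization of the deposited values again, centring each array on its median, keeping only genes above the median probe set, the mean of a gene's probe sets, every probe set tested, trended and robust variances, array weights, a plain test without moderation, an adjusted p of 0.01, and limma's treat against a 1.2-fold change. The array median as a covariate, and quantile normalization for the comparison of chromosomes, were added after the data were examined. All 35 distinct splits of the 8 arrays into 4 and 4 were refitted. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.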

Results

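Gene expression was measured on 8 arrays of normal human mammary epithelial cells, 4 from cultures with 10 µM tamoxifen for 48 h and 4 from vehicle cultures, to find which genes the drug regulates in cells that are not cancerous. The median log2 value per array lay between 6.23 and 6.32. Pearson correlations over all probe sets were 0.9961 to 0.9984 within groups and 0.9897 to 0.9951 between groups. The first principal component held 70.2% of the variance and separated the groups, and the next held 12.9%. No array was a copy of another, since any array shared at most 154 of 29096 values with another (equal in all decimals given).

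After tamoxifen, genes induced by type I interferon rose together and genes of mitosis and DNA replication fell together. The mean of 39 interferon response genes rose from 8.53 ± 0.11 to 9.72 ± 0.12 (log2, mean ± SD, n = 4), and 38 of them passed the genewise test. The mean of 39 mitosis genes went from 8.36 ± 0.12 to 6.96 ± 0.31, and all 39 fell. These were the largest shifts among 35 gene lists fixed beforehand, of which 15 shifted by camera at its preset correlation, 6 up (such as glycolysis and cholesterol biosynthesis) and 9 down (such as ribosomal proteins, the respiratory chain and NRF2 targets), and 0 with an estimated correlation. The estrogen receptor gene ESR1 and the classical estrogen targets PGR, GREB1 and TFF1 had log2 changes of -0.15, -0.064, -0.17 and 0.028. However, PGR (4.40 ± 0.065 in vehicle) and GREB1 (5.76 ± 0.057) were dim, and RMA compresses changes there. ESR1 (6.26 ± 0.059) and TFF1 (6.26 ± 0.14) also lay below the median probe set of 6.284 in vehicle.

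Of 18417 genes, 5027 (27.3%) changed at an adjusted p under 0.05, with 2060 higher and 2967 lower. The median size of these changes was 0.28 on the log2 scale, and 87.2% of them were under 1.5-fold. A change of at least 2-fold was found for 201 genes, 71 higher and 130 lower. In 29.4% of all genes the 4 tamoxifen arrays did not overlap with the 4 vehicle arrays, against 2.86% by chance, and 4624 of the changed genes were among them. The median log2 change over all genes was 0.0125, and the median spread within groups was 0.082.

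**Figure D1:**
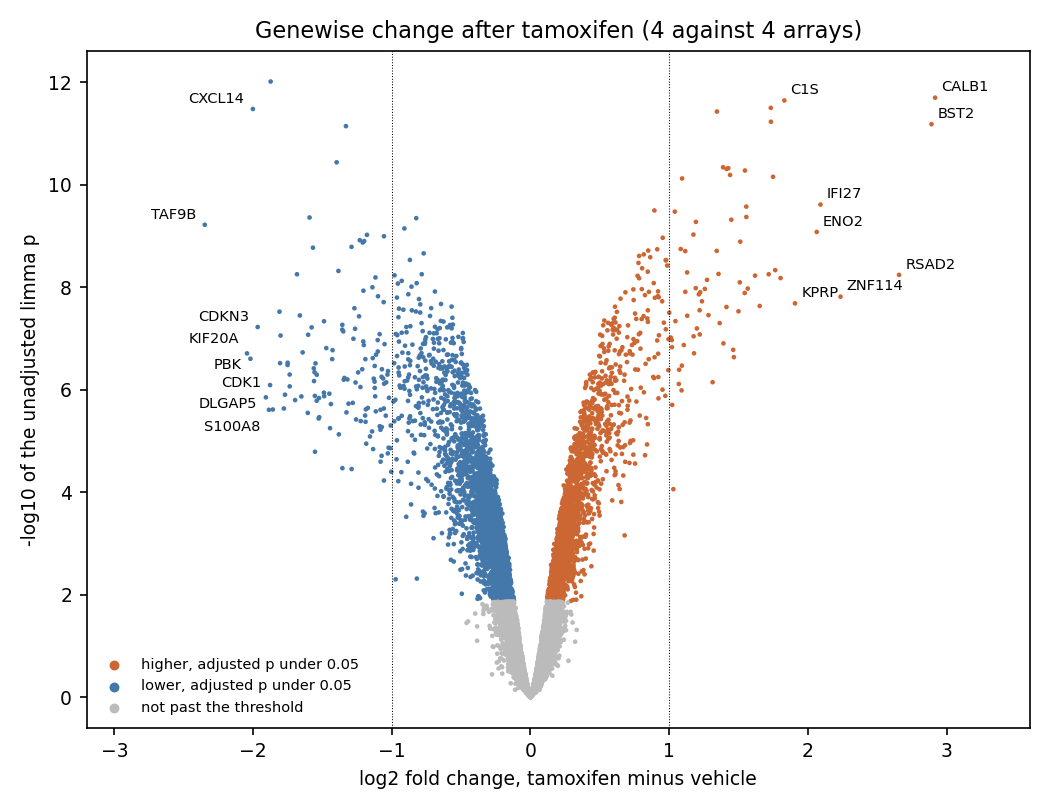
Log2 fold change of each gene (tamoxifen minus vehicle, horizontal axis) against the negative log10 of its unadjusted limma p (vertical axis), with genes past an adjusted p of 0.05 coloured by direction and dotted lines at 2-fold. The 16 labelled genes are those with the largest rises and falls, from CALB1 at 2.92 to TAF9B at -2.35.

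The largest rise was that of CALB1, which encodes the calcium-binding protein calbindin, from 5.84 ± 0.19 to 8.76 ± 0.10 (SD, n = 4), a 7.55-fold change (SE of the log2 change 0.088, adjusted p = 1.14e-08). It was followed by the interferon-induced genes BST2 (7.42-fold, adjusted p = 1.47e-08), which encodes the virus-tethering protein tetherin, and RSAD2 (6.31-fold, adjusted p = 1.67e-06), which encodes viperin. ZNF114, a zinc finger gene, rose 4.71-fold, the interferon-induced IFI27 4.26-fold, and ENO2, the neuronal form of the glycolytic enzyme enolase, 4.18-fold. KPRP, a gene of the keratinocyte cornified layer, rose 3.75-fold and C1S, a protease of the first complement component, 3.56-fold from 7.42 ± 0.025 to 9.25 ± 0.11.

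TAF9B, a component of the basal transcription machinery, fell the most, from 7.96 ± 0.13 to 5.61 ± 0.28 (SD, n = 4), and was 5.09-fold lower (SE 0.12, adjusted p = 4.12e-07). Its 2 probe sets hold the same value. Of the 7 others, 5 serve cell division: the mitotic kinesin KIF20A was 4.12-fold lower, the mitotic kinase PBK 4.05-fold, the phosphatase CDKN3 3.91-fold, the spindle gene DLGAP5 3.75-fold and the cyclin-dependent kinase CDK1 3.67-fold. The chemokine CXCL14 was 4-fold lower, from 8.74 ± 0.13 to 6.73 ± 0.045. S100A8, which encodes a calcium-binding protein of stressed epithelium and myeloid cells, was 3.69-fold lower, with more spread in the tamoxifen group (8.93 ± 0.54) than in the vehicle group (10.82 ± 0.17). The adjusted p of these 7 genes lay between 1.14e-08 and 6.92e-05.

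**Figure D2:**
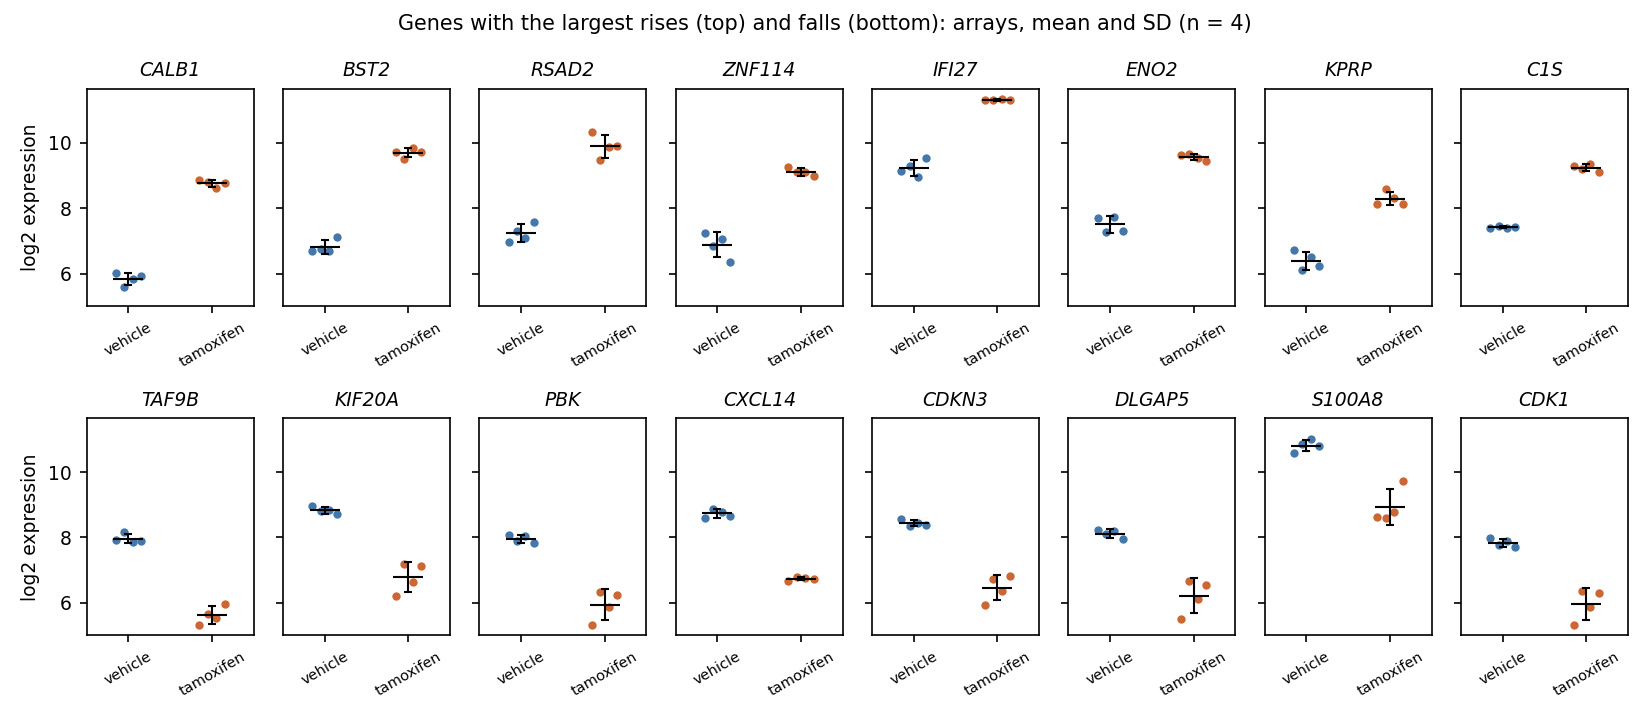
Log2 expression on each array (points) with the mean and SD of 4 arrays (bars) for the 8 genes with the largest rises (top) and the 8 with the largest falls (bottom). In every panel the 4 tamoxifen arrays lie on one side of the 4 vehicle arrays, and CALB1 has means of 8.76 and 5.84.

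In the type I interferon list, 38 of 39 measured genes rose, also when adjusted over the list alone, with a mean log2 change of 1.19. IFI35, an interferon-induced protein gene, rose 2.71-fold (adjusted p = 7.90e-08), beside BST2, RSAD2 and IFI27 above. The member that did not pass was IRF9, a transcription factor of the interferon signal, at 0.091 (adjusted p = 0.315). The shift had a camera adjusted p of 5.40e-38, and the adjusted p was 0.239 with an estimated correlation.

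In the list of antigen presentation and interferon gamma response, 8 of 17 measured genes rose and 2 fell, with the same counts adjusted over the list alone. B2M, the light chain of class I molecules, rose 1.67-fold and TAP1, a peptide transporter for them, 1.53-fold. The 2 that fell were HLA-DMA (-0.51), of the class II pathway, and the chemokine CXCL11 (-0.57). The mean log2 change was 0.17 (camera adjusted p = 0.00252; adjusted p = 0.239 with an estimated correlation).

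All 39 mitosis genes fell, by a mean of -1.39. CENPF, a kinetochore protein gene, was 3.17-fold lower and CCNB1, which encodes cyclin B1, 2.36-fold. Of 39 genes of DNA replication and S phase, 37 fell, by a list mean of -0.64. TYMS, the thymidylate synthase gene, was 2.32-fold lower and GINS4, of the replicative helicase, 1.84-fold. The 2 members not past the test were E2F2 (0.021) and SLBP (0.012). Counts adjusted over the list alone were the same for both lists. Camera adjusted p-values were 1.21e-30 and 5.06e-19, and the adjusted p was 0.239 with an estimated correlation for both.

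DNA repair genes fell in 24 of 36 cases (26 adjusted over the list alone, with 1 higher), with a list mean of -0.36. PARP1, a sensor of DNA breaks, was 1.74-fold lower and FANCI, of the Fanconi anemia pathway, 2.18-fold. Of 34 replication-dependent histone genes, 26 fell and 2 rose (27 and 3 adjusted over the list alone), with a mean of -0.51. H4C2 was 1.64-fold lower, while H2BC21 (0.61) and H4C8 (1.02) rose. Both lists had a camera adjusted p of 8.75e-10. With an estimated correlation the adjusted p was 0.306 for DNA repair and 0.239 for the histones.

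Glycolysis and hypoxia genes rose in 19 of 27 cases (21 adjusted over the list alone) and none fell, with a mean of 0.40. After ENO2, the member with the smallest p was SLC2A3, a glucose transporter, which rose 1.8-fold. Of 37 genes of the mitochondrial respiratory chain, 28 fell (33 adjusted over the list alone), with a mean of -0.25. NDUFB9 and NDUFB5, both of complex I, were 1.4-fold and 1.39-fold lower. Cytoplasmic ribosomal protein genes fell in 27 of 37 cases (34 adjusted over the list alone), with a mean of -0.23, led by RPS23 (1.43-fold lower) and RPS24 (1.42-fold lower). Camera adjusted p-values were 2.98e-12, 1.17e-12 and 2.39e-12, and each list had an adjusted p of 0.239 with an estimated correlation.

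Cholesterol biosynthesis genes rose in 12 of 21 cases (16 adjusted over the list alone), with a mean of 0.20. INSIG1, a sterol-regulated sensor of the pathway, rose 1.56-fold. The single member that fell was TMEM97, the sigma-2 receptor gene (1.41-fold lower). Among growth factor and immediate early genes, 13 of 22 rose, with the same count adjusted over the list alone, and 1 fell, with a mean of 0.22. SPRY2, a feedback inhibitor of growth factor signals, rose 1.52-fold, and the member that fell was EREG, an EGF receptor ligand (1.59-fold lower). Camera adjusted p-values were 1.09e-05 and 3.26e-05. With an estimated correlation the adjusted p was 0.279 for the former and 0.239 for the latter.

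Of 26 genes of NRF2 and oxidative stress, 18 fell and 3 rose, with the same counts adjusted over the list alone and a mean of -0.32. GSR, glutathione reductase, was 3.02-fold lower and SLC7A11, the cystine carrier that feeds glutathione synthesis, 2.31-fold. The 3 that rose were AKR1C1 (0.46), AKR1C2 (0.64), both steroid and carbonyl reductases, and HMOX1 (0.31), which degrades heme. Among 27 genes of ATF4 and the amino acid response, 13 fell and 5 rose (13 and 6 adjusted over the list alone). Its members with the smallest p belong to amino acid synthesis: PSAT1, of serine synthesis, was 3.66-fold lower (adjusted p = 1.14e-08) and ASNS, asparagine synthetase, 2.63-fold (adjusted p = 6.72e-08). The 5 that rose were VLDLR, TRIB3, PPP1R15A, DDIT4 and ATF3, by 0.15 to 0.58. The list's mean was -0.36 and its median -0.059. Unfolded protein response genes fell in 11 of 20 cases (14 adjusted over the list alone) with a mean of -0.17, among them the chaperone genes PDIA4 (1.43-fold lower) and HSP90B1 (1.2-fold lower), and SYVN1, of protein degradation, rose by 0.17. Camera adjusted p-values were 1.75e-07, 7.71e-04 and 7.77e-05 in this order, with an adjusted p of 0.239, 0.279 and 0.239 with an estimated correlation.

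**Figure D3:**
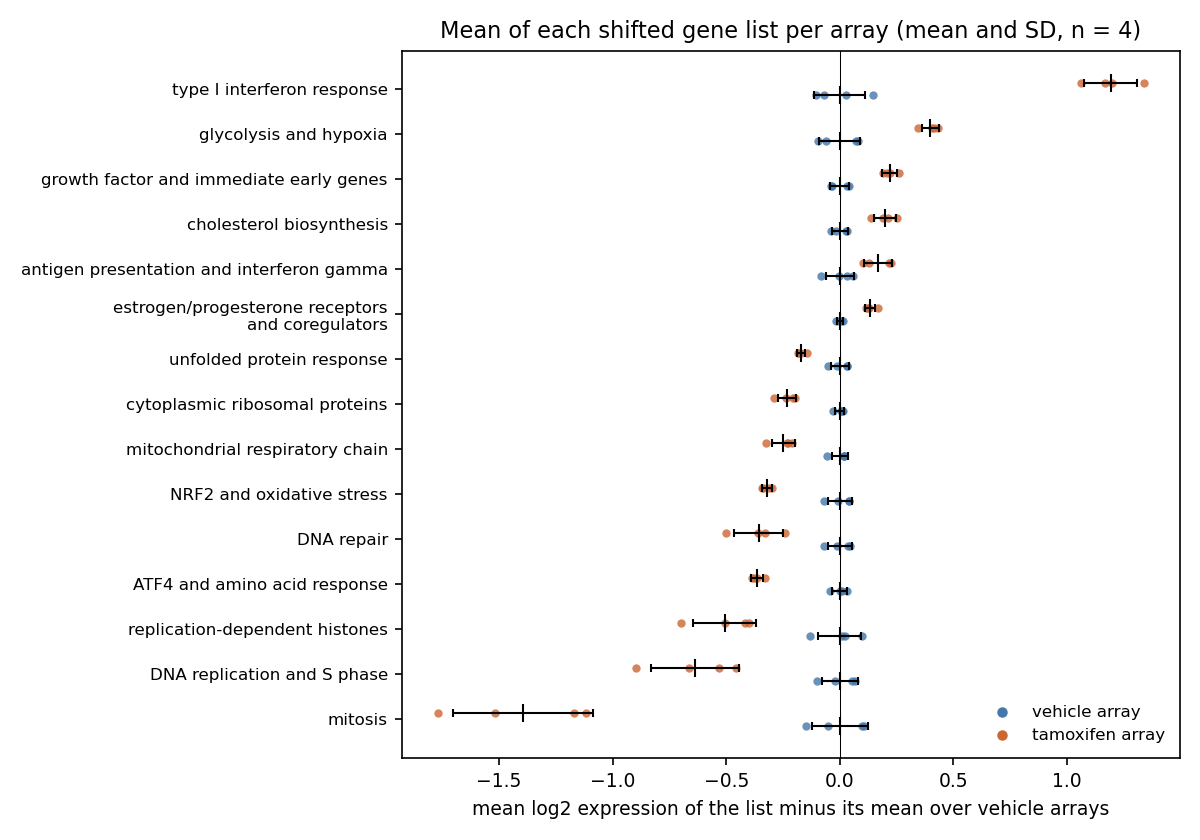
Mean log2 expression of each of the 15 shifted gene lists on every array, relative to the mean of the 4 vehicle arrays (horizontal axis), with points for arrays and bars for the mean and SD of 4 arrays. The type I interferon list lies 1.19 higher and the mitosis list 1.39 lower after tamoxifen. For mitosis the SD was 0.31 over tamoxifen arrays and 0.12 over vehicle arrays, a difference in spread that was not tested.

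ESR1, which encodes the drug's main target, had a log2 change of -0.15 (SE 0.046, 95% interval -0.25 to -0.047, adjusted p = 0.0325) at a level of 6.26 ± 0.059 in vehicle, below the median of 6.284 of all probe sets. Its dimmer probe set gave 0.12 (adjusted p = 0.19), and the mean of both gave -0.016 (adjusted p = 0.85). Without vehicle replicate 2, 3 or 4 or tamoxifen replicate 1 or 3, the adjusted p of ESR1 was 0.0784, 0.0982, 0.0577, 0.0821 and 0.0821. GREB1 had a change of -0.17 (adjusted p = 0.0231), and without vehicle replicate 2 or 3 or tamoxifen replicate 2 or 3 its adjusted p was 0.0787, 0.0566, 0.0524 and 0.0764. Over all alternatives the adjusted p ran from 0.0139 to 1 for ESR1 and from 0.00702 to 1 for GREB1. PGR (-0.064, 95% interval -0.17 to 0.042, adjusted p = 0.389) and TFF1 (0.028, 95% interval -0.22 to 0.27, adjusted p = 0.894) did not pass the test. CYP1A1, a target of the aryl hydrocarbon receptor, was 1.52-fold lower (adjusted p = 7.69e-05).

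In the list of estrogen and progesterone receptors and coregulators, 4 of 14 genes rose and 1 fell (6 and 1 adjusted over the list alone). The members that rose were NRIP1, a corepressor that is itself an estrogen target (1.7-fold, adjusted p = 5.54e-06), and the coactivators EP300 (1.19-fold), NCOA1 (1.15-fold) and CREBBP (1.1-fold); ESR1 was the member that fell. The mean was 0.13 (camera adjusted p = 0.0258; adjusted p = 0.239 with an estimated correlation). Of 25 estrogen receptor targets, 4 rose (NRIP1, GATA3, SIAH2 and CELSR2) and 8 fell (5 and 9 adjusted over the list alone), and the list did not shift, with a mean of -0.03, a median of 0.028 and a camera adjusted p of 0.69.

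The other 19 lists did not pass camera as a whole, although most held genes that moved in both directions. Among squamous differentiation genes, 11 of 33 rose and 7 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.0944). CDSN, which encodes corneodesmosin of the cornified layer, rose 3.07-fold, while S100A8 fell. Among NF-kB targets and inflammatory cytokines, 10 of 30 rose and 8 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.548), led by the matrix metalloproteinase MMP9 (3.32-fold higher). Of 32 genes of the TGF-beta and mesenchymal program, 9 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.102), with the integrin gene ITGA5 1.82-fold higher and TGFB2, TPM2, SPARC and CCN1 lower. Of 27 p53 targets, 11 fell and 5 rose (11 and 5 adjusted over the list alone; camera adjusted p = 0.122). GDF15, a stress-induced cytokine, was 2.45-fold lower, and those that rose were TP53I3, GADD45A, TP53INP1, PHLDA3 and PMAIP1. Of 34 lysosome genes, 10 rose and 6 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.195), with GPNMB 1.64-fold higher. Of 22 autophagy genes, 8 rose, led by the initiating kinase ULK1 (1.3-fold), and ATG3, ATG7 and WIPI1 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0866). Without vehicle replicate 1 the autophagy list had an adjusted p of 0.0308. Of 16 phospholipidosis markers, 7 rose and 3 fell, the latter ASNS, NUPR1 and SERPINA3 (8 and 4 adjusted over the list alone; camera adjusted p = 0.122).

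Among drug metabolism and transport genes, 8 of 24 fell, led by CYP1B1 (1.96-fold lower), and TIPARP, POR and ARNT rose (8 and 3 adjusted over the list alone). The list's mean was -0.11 and its median 0.013 (camera adjusted p = 0.376). Of 16 fatty acid synthesis genes, FADS2, ACSS2, ACSL1, LPIN1 and SCD rose and ACACA, ELOVL6, ME1 and ELOVL5 fell, with ACACA, the carboxylase that commits carbon to the pathway, 1.48-fold lower (6 each way adjusted over the list alone; camera adjusted p = 0.664). In the sterol efflux list, LPCAT3 (-0.43), ABCG1 and MYLIP fell among 10 genes, as when adjusted over the list alone, and the mean was -0.068 and the median 0.026 (camera adjusted p = 0.445). Of 17 heat shock genes, CRYAB and DNAJB1 rose and HSPD1 (-0.49), HSPE1, BAG3 and HSP90AB1 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.383). Of 27 apoptosis regulators, BIRC2 (0.44), BMF, TNFSF10 and PMAIP1 rose and BID, BCL2A1, BAX, CASP10 and BCL2L11 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.815). None of 11 metallothionein genes passed the test by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.743). Its smallest p was that of MT1F, at 0.20 (adjusted p = 0.0641), which was 0.0149 without tamoxifen replicate 2.

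Markers of cell types that such cultures can hold moved little as groups. Of 20 basal and myoepithelial markers, NT5E, ACTA2, MME, LAMB3 and TAGLN rose and MYLK (-0.60), S100A2 and DST fell (5 and 4 adjusted over the list alone; mean -0.006, median 0.02, camera adjusted p = 0.758). Of 28 luminal markers, 8 rose and 3 fell, the latter ALDH1A3 (-0.82), EPCAM and ESR1 (9 and 3 adjusted over the list alone; mean 0.069, camera adjusted p = 0.11). A dimmer probe set of ALDH1A3 gave 0.042 (adjusted p = 0.731). Fibroblast markers FAP (0.43), PDPN and DCN rose and THY1, MFAP5 and FBLN1 fell among 16, as when adjusted over the list alone (mean 0.043, camera adjusted p = 0.386). Of 19 leukocyte markers, CD68, a lysosomal protein gene also used for macrophages, rose 1.5-fold from 10.13 ± 0.076, and CSF1R 1.26-fold from 6.04 ± 0.086, as when adjusted over the list alone (mean 0.081, camera adjusted p = 0.122). None of 14 endothelial markers passed the test by limma either way of adjusting (mean 0.03, camera adjusted p = 0.381). ROBO4 had the smallest p among them, at 0.20 (adjusted p = 0.0737), which was 0.0443 without tamoxifen replicate 2. Of 12 adipocyte markers, FABP4 (-0.32) fell, at a level near the floor of the arrays, as when adjusted over the list alone (mean -0.019, camera adjusted p = 0.713).

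In all, 15 of 35 lists shifted, 6 up and 9 down, by camera at its preset correlation, and 17 had an unadjusted p under 0.05. With an estimated correlation 0 of them passed, and fry called 24 for a common direction and 32 for either. Other splits of the 8 arrays gave camera counts of 11 to 17 lists where 3 arrays of a group stayed together, which keeps part of the real difference, and of 0 to 6 where each side held 2 arrays of each group, and no other split gave more than 1 changed gene. Against a change of 1.2-fold, limma's treat called 908 genes, 345 higher and 563 lower, and the calls of HSP90B1, EP300, ULK1, FAP, LPCAT3, BIRC2 and FABP4 ended there.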

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

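The relation between interferon and mitosis genes within the groups was chosen for testing after the data were examined, while the tests of explanations given here were set before their results were seen.

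An array stood apart from the other 3 of its group in 11 of the 204 groups of 4 arrays that were checked (35 list means and 67 genes, in each group). Chance alone gives about 1 in 20, or 10.2, so their total is near chance, but 5 lay on vehicle replicate 4 and 4 on tamoxifen replicate 1, against 1.3 expected per array. The checked values are not independent of each other, and whether these arrays differ in quality was not tested. Without the former 5126 genes changed, and without the latter 4373. Vehicle replicate 4 was apart for the mean of fatty acid synthesis genes (9.02, others 9.088 to 9.098), the respiratory chain (9.445, others 9.516 to 9.519), ribosomal proteins (10.926, others 10.961 to 10.968), BST2 (7.115, others 6.699 to 6.739) and GINS4 (6.502, others 6.871 to 6.888). Tamoxifen replicate 1 was apart for the mean of basal markers (9.837, others 9.87 to 9.875) and luminal markers (7.065, others 7.003 to 7.011), for GDF15 (7.874, others 8.067 to 8.078) and for SPRY2 (10.217, others 10.354 to 10.371). S100A8 on tamoxifen replicate 4 was 9.739, against 8.602 to 8.766 on the others. EP300 on vehicle replicate 1 was 8.448, against 8.384 to 8.393.

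Probe sets outside the gene tests also differed between the groups. Of 7882 probe sets without a symbol, 473 passed the threshold, 192 higher and 281 lower with tamoxifen, 12 of them at least 2-fold. Of 1754 probe sets with several symbols, 358 passed, 137 higher and 221 lower, 13 of them at least 2-fold.

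The small common falls of ribosomal protein and respiratory chain genes could come from an offset between the groups that depends on brightness, since these genes are bright. After the trend of log2 change on mean expression over all genes was subtracted, the mean of the ribosomal list was -0.217 (SE over genes 0.022, -0.232 before) and that of the respiratory chain -0.237 (SE 0.018, -0.249 before). An offset of this kind is therefore not the whole cause. A slower growth of the treated cells, and an effect of the drug on ribosomes or mitochondria, stay open as untested explanations.

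Within the groups, arrays with a higher mean of interferon genes had a lower mean of mitosis genes. Over the 8 arrays' deviations from their group means, r was -0.868 (exact within-group permutation p = 0.00347, adjusted over 3 relations 0.0052; Spearman's rho -0.881, p = 0.00694), and -0.725 without the 2 farthest arrays. The array median also followed the interferon deviation (r = 0.945, p = 0.00694; rho 0.929, p = 0.00694; 0.899 without the 2 farthest), so residual differences in the arrays' distributions could produce both. After quantile normalization again the SD of the mitosis mean over tamoxifen arrays was 3.16 times that over vehicle arrays (2.49 before). Each SD rests on few arrays and the difference in spread was not tested, so no conclusion is drawn from it. The r between interferon and mitosis deviations was then -0.819 (p = 0.00347; rho -0.786, p = 0.00694; -0.653 without the 2 farthest). This argues against differences in the arrays' distributions as the cause of that relation. The data may therefore hold cultures that differed in the degree of a single response, or cultures of unlike density or RNA quality, which the labels do not separate.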

How the results depend on the processing

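Among the alternatives of this section, the array median as a covariate was chosen after the data were examined, and all others were planned. Most results kept their direction and side of the threshold: over all alternatives 1229 values of named genes and 545 of list shifts did, while 9 and 29 newly passed and 26 and 15 no longer did. The count of changed genes ran from 4223 (each array centred on its median) to 6258 (array median as a covariate), apart from stricter thresholds, and 4185 and 5027 of those genes were among the 5027. Quantile normalization again gave 5584, with 48.1% higher against 41%. With each repeat number as a replicate block, 4356 genes and 201 at least 2-fold passed and 15 lists shifted. Same-numbered arrays did not deviate together (r = -0.35, -0.2, -0.07 and 0.23), and 1 of 8 arrays correlated best with its own number, so the numbers give no sign of a pairing. At an adjusted p of 0.01, 1335 genes were higher, and treat against a 1.2-fold change left 908 genes, 345 higher and 563 lower. Of the 5027 changed genes 87.2% had changed by under 1.5-fold. Leaving out each array in turn gave 4246 to 5126 changed genes, 1696 to 2017 higher, 2472 to 3139 lower, 171 to 219 at least 2-fold and 15 to 16 shifted lists. Camera with an estimated correlation called 0 lists. For the 15 shifted lists the estimates ran from -0.0248 (receptors and coregulators) to 0.8 (mitosis), with 0.561 for interferon, against the preset 0.01. Their unadjusted camera p ran from 0.0168 (interferon) to 0.131 (DNA repair). A higher correlation weakens camera's p, but its share in the loss was not tested. For receptors and coregulators the estimate lay below the preset, yet the unadjusted camera p went from 0.011 to 0.0355. A higher correlation is therefore not the cause for that list. Fry, which does not compare a list with other genes, called 24 for a common direction and 32 for either. The direction of the test turned for estrogen receptor targets above the median probe set (mean against other genes -0.001), apoptosis regulators by fry (0.022), adipocyte markers (-0.042 to 0.023 over the arrays left out, 0.023 without tamoxifen replicate 2) and TFF1 (-0.034 to 0.138; -0.033, -0.034 and -0.033 without vehicle replicate 1, tamoxifen replicate 1 and tamoxifen replicate 4); the cause was not tested. The mean of heat shock genes against other genes also changed sign (-0.02 to 0.017), with the test's direction kept. Signal over background limits dim genes: of the dimmest 1842 genes 1.2% and 1.6% were called higher and lower, against 21.8% and 24% of the brightest 1842.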

Other observations

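The additional gene lists, the comparison of chromosomes, the exact test of list means, the test for leukocyte RNA and the background for interferon genes were chosen after the data were examined. So were the genes named in the next 2 paragraphs, and PTPRC, LYZ and CD86. P-values of the additional lists were adjusted over these lists alone. They are therefore not comparable with the adjusted p-values of the lists fixed beforehand. Some of the additional lists hold genes already named above as changed, such as MMP9, C1S and ITGA5. Their p-values can therefore be too small and are descriptive only.

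Some genes of complement and of the extracellular matrix changed with tamoxifen. Of 22 complement genes, 5 rose and 1 fell (camera adjusted p = 0.00365; adjusted p = 0.0848 with an estimated correlation). The proteases of the first component, C1R and C1S, rose 3.33-fold and 3.56-fold, their inhibitor SERPING1 2.54-fold and factor B, CFB, 2.02-fold, and C5 fell by 0.43 on the log2 scale. Of 21 matrix metalloproteinases and their inhibitors, 8 rose and none fell (camera adjusted p = 0.000116; adjusted p = 0.0458 with an estimated correlation), led by MMP10 (3.49-fold) and MMP9 (3.32-fold). Among 19 integrins, 5 rose and 2 fell (camera adjusted p = 0.0401; adjusted p = 0.0872 with an estimated correlation), with ITGB3 2.92-fold higher and ITGA4 2.61-fold lower. The interleukin 1 family did not shift (4 of 15 rose, 3 fell; camera adjusted p = 0.322), but IL36B rose 2.94-fold and IL33 was 2.12-fold lower. Both were dim, with IL36B at 4.96 ± 0.15 in vehicle and IL33 at 5.11 ± 0.20 with tamoxifen.

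Of 19 cytosolic aminoacyl-tRNA synthetases, 18 fell, among them AARS1 and WARS1 of the ATF4 list (camera adjusted p = 5.74e-11; adjusted p = 0.0872 with an estimated correlation), and of 27 proteasome genes 14 did (camera adjusted p = 6.08e-06; adjusted p = 0.24 with an estimated correlation). Of 6 APOBEC3 cytidine deaminases, some of which interferon induces in other cells, 4 fell and none rose (camera adjusted p = 0.00141; adjusted p = 0.0872 with an estimated correlation), and APOBEC3B was 3.21-fold lower (SE 0.11, adjusted p = 1.66e-06). Of 21 nucleic acid sensors and adaptors 9 rose and STING1 fell by 0.32 (camera adjusted p = 0.00141; adjusted p = 0.0872 with an estimated correlation). Since RIGI, IFIH1 (2.56-fold) and IRF7 also belong to the type I interferon list, this partly repeats its result. Of 13 interferon receptors and kinases, 4 rose (JAK2, TYK2, SOCS1 and USP18), and that list did not pass (camera adjusted p = 0.0971).

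No other of the 35 splits of the 8 arrays into 4 and 4 came near the real one in single genes. The real split called 5027 genes, 2060 higher and 2967 lower, and 201 at least 2-fold. The highest other called 1, 1, 1 and 0 by limma. Higher and lower are exchanged in a mirrored split, so the larger of both was taken. Only 1 split, the real one, therefore gave as many of each. However, 35 splits can give no exact p below 0.0286, so chance is not excluded for these counts. Every other split also mixes both groups on each side, which puts the real difference into the spread limma tests against. Low counts there are therefore no pure measure of chance. Nor can the splits tell the drug from another difference between the groups, such as a batch. The count of shifted lists did not set the real split apart. The real split gave 15, the highest other 17, and 4 of the 35 splits gave as many, so chance cannot be excluded for the number of lists by camera over all splits. The 16 splits with 3 arrays of one group and 1 of the other on each side keep part of the real difference and gave 11 to 17 lists, so they are no pure measure of chance, while the 18 splits with 2 arrays of each group on both sides gave 0 to 6. Taken list by list, the difference of the 15 list means was larger in the real split than in any other, with an exact permutation p of 0.0286 for each, the smallest that 35 splits can give (adjusted over the 35 lists 0.0435), and 23 lists in all reached it. The others were lysosome, autophagy, p53 targets, drug metabolism, NF-kB, TGF-beta, luminal markers and phospholipidosis, which camera did not call. This exact test does not compare a list with other genes, and 29.4% of single genes also had no overlap between groups.

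The interferon response has several candidate sources. RNA of leukocytes would bring their other transcripts, but 2 of 19 leukocyte markers rose, and the mean of the 19 was 0.081 with an upper 95% bound of 0.153. This bound was taken over the 19 genes, not over arrays, and treats them as independent. Their mean level in vehicle was 5.66, below the median probe set, where RMA compresses changes. A small share of leukocyte RNA is therefore not excluded. The general leukocyte gene PTPRC stayed at 3.76 ± 0.075 against 3.76 ± 0.028 and LYZ at 4.10 ± 0.12 against 4.10 ± 0.095, although CD86, found on antigen-presenting cells, rose 3.36-fold. Interferon made by the cells themselves is a candidate source. The 16 measured interferon genes, IFNG included, did not shift as a list (camera adjusted p = 0.146, and 0.456 with an estimated correlation). Of the 15 type I and III genes among them 3 rose, IFNK, IFNL1 and IFNL2, by 0.34 to 0.42. At the share of genes of like brightness 0.518 would be called higher (exact one-sided p = 0.0105). Without IFNL2, a close relative of IFNL1 that need not be independent of it, 2 of 14 rose (exact one-sided p = 0.0682). Interferon from the cells would give such rises, but interferon genes that rose as part of the response would too, only 4 of the 15 genes lay above the median probe set in either group, and a direct effect of the drug or an earlier wave of interferon stays open.

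More of the changed genes rose on chromosome 19 than elsewhere. Of its changed genes, 180 rose and 110 fell (62.1% rose), against 39.7% on the other chromosomes (Fisher's exact p = 1.16e-13, 2.67e-12 after correction for 23 chromosomes). Among all genes tested, 180 of 1309 rose and 110 fell there, against 1879 and 2853 of 17056 on the other chromosomes. The difference therefore lay more in fewer falls than in more rises. After quantile normalization again the shares were 70.3% and 46.6%. A hypothesis is that the zinc finger genes clustered on this chromosome rose together. Of those that changed 37 rose and 6 fell (86%), against 29 and 25 on other chromosomes. However, of all 242 only 37 rose and 6 fell, against 143 and 104 of the chromosome's 1067 other genes. They thus differed from these more in few falls than in many rises. Without zinc finger genes 57.9% of the changed genes of chromosome 19 still rose (95% exact interval 51.5 to 64.1). Zinc finger genes may therefore add to the pattern but are not its whole cause. Neighbouring genes are not independent, so the p-values are too small, and a bias by base composition, which is rich in G and C on this chromosome, was not tested.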
